A study of Mus musculus with 6 samples.

How the data were processed

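Total RNA from 6 cultures of C57BL/6 bone marrow-derived macrophages was hybridised to Affymetrix 1-colour arrays, 1 array per sample, with 2 biological replicates in each of 3 groups, per the labels. Groups and replicate numbers came from the sample titles. The source label of tolerant + LPS replicate 1 gives LPS treatment without the pretreatment that its title and protocol give, and the protocol of untreated replicate 2 omits the stimulation time. The labels name biological replicates but not whether equal numbers share an animal or day.

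The deposited intensity values are MAS5 signals on a linear scale, made by the authors with MAS5 per the submitters' processing notes (the version is not given in the sources used here). Each array had a 2% trimmed mean of 500, computed from the values, so the authors' scaling was kept. Detection calls were not used here. A scaling of this kind sets each array's trimmed mean, which leaves out the brightest 2% of probe sets. A rise of bright genes that stay within the trim lowers the values of the rest.

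Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 several and 9211 none, and 34754 of the first had a gene identifier in the reference gene table. The 64 control probe sets and those with no or several symbols were left out. Values were taken as log2(signal + 16), which understates the fold of dim genes. Each of 18193 genes was represented by its probe set with the highest mean, and genes with a mean under the 40th percentile (a signal of about 64.02) were left out, which left 10916. Probe sets of 1 gene disagreed in sign for Ppp1r12b, Gas6 and Birc3 among the named genes, and their values are uncertain. For other genes they could differ in size, so a bound written "at least" holds for the probe set used, not for every probe set of the gene.

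Group means were fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a mean-variance trend; 3 residual and 4.18 prior degrees of freedom), and p-values were Benjamini-Hochberg adjusted over genes within each comparison at 0.05. Every adjusted p of a single gene is limma's. The ± values of log2 differences are standard errors of this fit. An exact two-sided test of 2 against 2 arrays cannot go below 0.333, so no such test was used for single genes. Background was the 95th percentile of 27 unspiked bacterial control probe sets on each array. Where both arrays of the dimmer group lay at or under it, a fold is given as "at least", computed against the higher of background and the measured value.

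The fixed lists were 18 response and macrophage lists and 9 lists of other cell types. The first 18 were tested with camera (inter-gene correlation 0.01), adjusted over 54 tests, with an estimated correlation as an alternative. Of the 54, 35 passed, and 6 with an estimated correlation. A call lost under that alternative does not by itself show correlation among the members of a list. Shares of LPS-induced genes that were lower were compared between lists by Fisher's exact test, adjusted over the 10 lists with at least 5 induced members. Named genes were chosen by a fixed rule: the called genes with the largest non-overlapping changes (12 up and 6 down, 12 each way and 6 each way in the 3 comparisons), the 8 induced genes with the lowest and the 8 with the highest retained response, up to 4 members per list, and a panel of 16 genes. Of that panel Fpr1 and Camp were not analysed here, since no single-symbol probe set above the filter represented them. The lists, the rule, the tests of the comparisons and the alternatives were fixed before the data were examined.

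The fit was tested on simulated data with 200 changed genes among 10916. For naive + LPS against untreated it recovered 11.9% of log2 changes of 1, 82.1% of 2 and 100% of 4, with 16 false calls. For tolerant + LPS against naive + LPS it recovered 11.9%, 68.7% and 97%, with 6 false calls, and against untreated 11.9%, 79.1% and 98.5%, with 7. Camera found a list shifted by 1 in each comparison, and an unchanged list fell under an unadjusted 0.05 in 1 of the 3 (0.0356).

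Alternatives were pseudocounts of 1 and 64, median centring, quantile normalization, no filter or the 60th percentile, every probe set, the mean over probe sets, leaving out probe sets shared between transcripts or genes, no trend, a robust trend, fits of 2 groups, array weights, a replicate block, each array left out, a 2-fold minimum and an adjusted p under 0.01. Deviations of replicates from their group means correlated across groups at 0.496, 0.213 and 0.3, but with only 2 numbers this does not show that equal numbers pair the cultures. The replicate number, which the 18S controls separate, was used as a batch only in the replicate block alternative. The main fit has no block. Figures were drawn with matplotlib 3.10.9.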

Results

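Gene expression was measured in mouse bone marrow-derived macrophages, which are phagocytes grown here from C57BL/6 marrow progenitors for 7 days in medium with M-CSF, the macrophage growth factor. Lipopolysaccharide (LPS) is the bacterial cell wall component sensed by Toll-like receptor 4. The 6 arrays formed 3 groups of 2 biological replicates. Untreated cells received no LPS. Naive + LPS cells received 10 ng/ml LPS for 4 hours. Tolerant + LPS cells were first held in 100 ng/ml LPS for 24 hours, washed, and then given 10 ng/ml LPS for 4 hours. The design asks which genes respond to a first exposure and how that response differs in cells that have met LPS before. No array of pretreated cells without the second stimulus was analysed here, so what remained of the first exposure cannot be separated from the response to the second.

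The deposited values are MAS5 signal intensities, and every array had a trimmed mean of 500. The 2 arrays of a group correlated at r = 0.948 (untreated), 0.952 (naive + LPS) and 0.938 (tolerant + LPS) across the 10916 genes tested, and each array was closest to the other array of its group. The number of arrays, 2 per group, limits the precision. The background level, taken from unspiked bacterial control probe sets, lay between a signal of 36 and 80.1 and was highest on tolerant + LPS replicate 1. The 18S ribosomal RNA control (5′ probe set) separated the replicate numbers in every group. It read 7850 and 976.8 in untreated, 5110 and 990.2 in naive + LPS, and 11720 and 461.4 in tolerant + LPS cells, for replicates 1 and 2. The replicate number was therefore treated as a possible batch that holds all 3 groups, in an alternative fit with a replicate block. The main fit has no block. Of 9 lists of markers of other cell types, 8 had median signals between 7.73 and 103 on every array. Some of their members still lay above background. The share ran from 2 of 10 (mast cell and basophil list, naive + LPS replicate 1) to 11 of 13 (B cell list, tolerant + LPS replicate 2). The stromal list differed between the replicate numbers: its median was 34.1, 41.1 and 66.5 on the replicate 1 arrays of the 3 groups, with 6, 5 and 6 of 15 members above background, and 160, 161 and 113 on the replicate 2 arrays, with 13, 14 and 12. Of its members, chosen after their values were seen, Sparc read 7.505, 4.63 and 12.37 on replicate 1 and 856.2, 694.8 and 296.2 on replicate 2, and Col1a1 4.697, 16.47 and 4.884 against 479.9, 355.2 and 125.7.

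In naive cells, 4 hours of LPS raised most of the cytokine, chemokine and interferon-stimulated genes tested. Il6, which encodes the pyrogenic cytokine interleukin-6, rose by a log2 difference of 9.18 ± 0.43 (SE, n = 2 per group) from signals of 3.578 and 12.22 to 16040 and 11520, at least 243-fold given the background. Cxcl11, a T cell chemokine, rose at least 256-fold (8.99 ± 0.28), and Ptgs2, the inducible cyclooxygenase, at least 91.3-fold (7.48 ± 0.52). Of the interleukin-1 genes, Il1a rose at least 72.5-fold and Il1b by 6.98 ± 0.32, and Nos2, the inducible nitric oxide synthase, rose at least 44.6-fold. The largest falls were of Sesn1 (-6.65 ± 0.48, with 1 of the 2 naive + LPS arrays at background), Arhgap19 (-5.81 ± 0.30, 1 array), the chemokine receptor gene Cxcr4 (-5.62 ± 1.30, 1 array), Zfp36l1 (-4.92 ± 0.43), the circadian transcription factor gene Dbp (-4.77 ± 0.31) and Gpr160 (at least 16.2-fold). Other probe sets of the same gene gave smaller changes for Cxcl11 (3.10), Ptgs2 (5.58) and Sesn1 (-1.60 on the least changed of its 4).

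Of 19 cytokine genes tested, 15 rose, none fell and 4 did not pass (15 rose when adjusted over the list alone). Tnf rose by 5.60 ± 0.32 and Il12b, a subunit of interleukin-12, by 4.04 ± 0.64 (1 of 2 untreated arrays at background). Of 19 chemokine genes 14 rose (15 adjusted over the list alone), among them Cxcl10 (6.27 ± 0.24), Ccl5 (6.21 ± 0.38) and Cxcl2 (3.48 ± 0.34). Of 40 interferon-stimulated genes 38 rose (38 adjusted over the list alone), with a median log2 difference of 2.81. These included the antiviral genes Mx1 (5.58 ± 0.28) and Oasl1 (6.14 ± 0.38), and Ifnb1, interferon beta itself, rose by 2.49 ± 0.64. Among feedback inhibitors, 20 of 32 rose and 1 fell (23 and 3 adjusted over the list alone). Those that rose included Socs3, a suppressor of cytokine signalling (7.04 ± 0.23), Il1rn, the interleukin-1 receptor antagonist (5.03 ± 0.19), and Tnfaip3, the ubiquitin editor A20 (4.08 ± 0.27). In the inflammatory metabolism list 20 of 31 rose (21 adjusted over the list alone), including the collagenase Mmp13 (6.23 ± 0.22), the lipase Lipg (5.96 ± 0.45, 1 of 2 untreated arrays at background), Sod2 (3.12 ± 0.21) and Acod1, which makes itaconate (6.97 ± 0.96). Of 24 antimicrobial genes 10 rose (10 adjusted over the list alone), with the siderophore-binding Lcn2 and the complement factor Cfb both at 4.26 (for Lcn2, 1 of 2 untreated arrays was at background).

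Of 33 Toll-like receptor pathway genes 14 rose (14 rose and 1 fell adjusted over the list alone), among them Traf1 (5.00 ± 0.24), Nfkb2 (3.09 ± 0.27, and 1.32 on its other probe set) and Myd88 (1.89 ± 0.20). Of 26 antigen presentation genes 10 rose (11 adjusted over the list alone), with the costimulatory Cd40 at 6.51 ± 0.31 and Cd86 at 3.42 ± 0.24. In the apoptosis and survival list 10 of 22 rose and 1 fell (12 and 2 adjusted over the list alone), with Cflar at 2.80 ± 0.30. Of 37 cell-cycle genes 2 fell, Mcm2 (-2.04 ± 0.54) and Cenpa (-1.75 ± 0.48), and none did adjusted over the list alone or after median centring, while 8 fell with the replicate block. Of 30 cholesterol and lipid genes 5 fell (5 adjusted over the list alone), namely Mylip, Pparg, Scd2, Fads1 and Dhcr7. None of 37 oxidative phosphorylation genes passed.

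In the immediate early list 4 of 26 genes rose and 2 fell (7 and 2 adjusted over the list alone). Of its transcription factor genes, Junb (2.65 ± 0.31) and Cebpb (2.21 ± 0.33) were higher and Klf2 (-1.43 ± 0.27) lower. Of 30 scavenger uptake genes 6 rose and 1 fell (6 and 1), including the scavenger receptor Msr1 (1.53 ± 0.22) and the Fc receptor Fcgr1 (1.26 ± 0.21). Of 24 macrophage identity genes 2 rose and 2 fell (2 and 2), with the myeloid transcription factor gene Cebpa at -3.34 ± 0.50. Of 14 alternative activation genes 2 rose and 3 fell (4 and 4), with the interleukin-4 receptor gene Il4ra at 2.41 ± 0.23 (0.31 to 2.46 over its probe sets) and Pparg at -2.94 ± 0.40. Of 31 lysosome and phagocytosis genes 1 rose and 3 fell (1 and 2; 1 and 1 after median centring), and of 49 chromatin modifier genes 1 rose and 5 fell (0 and 4; 3 and 3 after median centring; 3 and 12 with the replicate block), among them the methyltransferase genes Setd7 (-2.89 ± 0.29), Dnmt3a (-1.52 ± 0.25) and Dnmt1 (-1.96 ± 0.41). The scavenger uptake list passed as a whole, upwards (camera adjusted p = 0.0344, and 0.397 with an estimated correlation), but after quantile normalization it pointed down without passing (0.911). The immediate early list passed upwards (0.0275, and 0.176 with an estimated correlation) but not after median centring (0.0796).

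With limma's camera, Benjamini-Hochberg adjusted over 54 list tests, cytokines (adjusted p = 5.37e-16), chemokines (5.3e-16) and interferon-stimulated genes (1.64e-38) were higher than the other genes. With an estimated correlation the adjusted p was 0.0812, 0.055 and 0.147. The feedback inhibitors and inflammatory metabolism lists (both adjusted p = 0.0407) and the antimicrobial list (0.0459) held with an estimated correlation. The median of cytokines was 3.20 and 3.55 in replicate sets 1 and 2, of chemokines 2.86 and 3.86, and of interferon-stimulated genes 2.40 and 3.17. The cell-cycle list did not pass (adjusted p = 0.212). It passed downwards with the replicate block (0.0175), after median centring (0.0135), without the filter on low genes (0.0193), and without untreated replicate 2 (1.63e-05) or naive + LPS replicate 1 (0.000158). Without untreated replicate 1 (0.301) or naive + LPS replicate 2 (0.517) it pointed up without passing, and with an estimated correlation it did not pass (0.833). With limma at an adjusted p under 0.05, 800 genes rose and 1287 fell in naive + LPS cells. The median of all genes lay at -0.31 under the authors' scaling, and the balance turned with it: after centring each array on its median, 1153 genes were higher and 537 lower, so the share of higher calls went from 38.3% to 68.2%. With the replicate number as a block the counts were 1024 and 2008. Leaving out 1 array gave 507 and 385 (without untreated replicate 1), 419 and 233 (untreated replicate 2), 486 and 544 (naive + LPS replicate 1) or 455 and 466 (naive + LPS replicate 2).

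**Figure D1:**
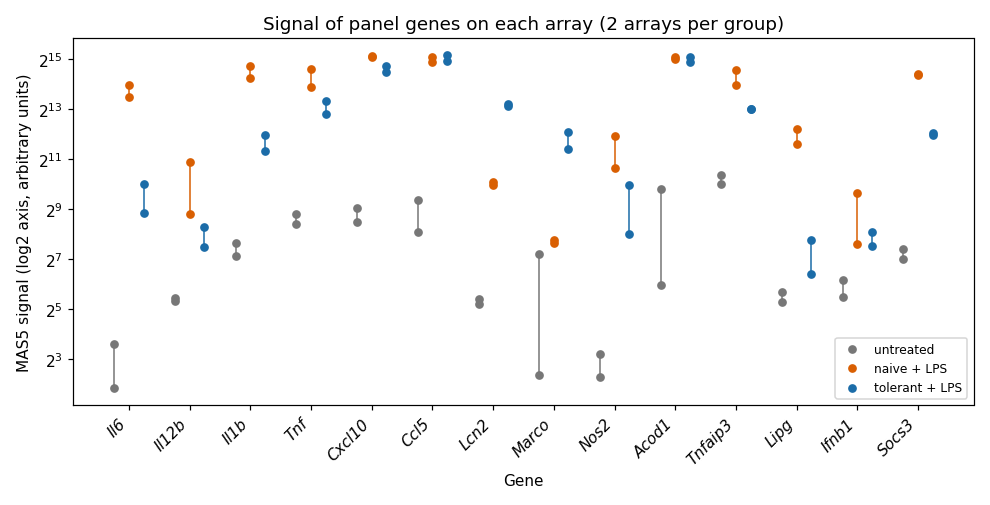
MAS5 signal on a log2 axis for the 14 panel genes tested, 1 point per array and a line joining the 2 arrays of each group. Il6 lies at 16040 and 11520 in naive + LPS and at 457.4 and 1019 in tolerant + LPS cells, and Lcn2 and Marco are highest in tolerant + LPS cells.

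Tolerant macrophages given LPS again had lower levels of several inflammatory genes than naive cells given LPS once, and higher levels of some antimicrobial genes. Il6 was lower by a log2 difference of -4.28 ± 0.43 (19.4-fold, n = 2 per group), Mmp13 by -4.57 ± 0.22, Lipg by -4.64 ± 0.45 and Il1b by -2.85 ± 0.32. Lcn2 was 8.79-fold higher (3.14 ± 0.24) and Marco, a scavenger receptor for bacteria, 15.4-fold higher (3.94 ± 0.84). Ccl5 (0.05 ± 0.38), Acod1 (-0.06 ± 0.96) and Cxcl10 (-0.50 ± 0.24) did not pass the test, and the sign of Ccl5 and Acod1 turned under some settings. The mannose receptor gene Mrc1 was lower by -4.94 ± 0.29.

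Of 19 cytokine genes 9 fell, none rose and 10 did not pass (12 fell adjusted over the list alone). Besides Il6 and Il1b these included Csf1, the macrophage growth factor (-2.78 ± 0.29, and -2.78 to -1.35 over 4 probe sets), and Tnfsf10 (-3.52 ± 0.38, and -3.52 to -2.41 over 3). Tnf (-1.19 ± 0.32, adjusted p = 0.0652, limma) and Il12b (-1.91 ± 0.64, 0.111) did not pass, but did with the replicate block (0.036 and 0.0415). Tnf differed by -1.10 and -1.27 and Il12b by -1.26 and -2.57 in replicate sets 1 and 2, and over the alternatives the adjusted p ran from 0.036 to 0.279 and from 0.0415 to 0.4. Of 19 chemokine genes 2 fell (2 adjusted over the list alone), Ccl6 (-1.39 ± 0.22) and Cxcl11 (-1.35 ± 0.28). Of 40 interferon-stimulated genes 6 fell (11 adjusted over the list alone), among them the guanylate-binding genes Gbp7 (-1.91 ± 0.25) and Gbp3 (-1.30 ± 0.24). Ifnb1 was not called (-0.76 ± 0.64, and 0.22 without naive + LPS replicate 1). Of 24 antimicrobial genes 6 rose and none fell (9 and 3 adjusted over the list alone; 4 and 2 after median centring), including Cfb (1.82 ± 0.27) and the haemoglobin-binding Hp (2.35 ± 0.43). The antimicrobial list did not pass as a whole (camera adjusted p = 0.19, and 0.329 with an estimated correlation). Of 32 feedback inhibitors 8 fell and 2 rose (10 and 3 adjusted over the list alone). Socs3 (-2.38 ± 0.23), Socs1 (-2.95 ± 0.45), Dusp2 (-3.47 ± 0.60) and Tnfaip3 (-1.27 ± 0.27) fell, and Irak3, an inhibitor of Toll-like receptor signalling, rose (1.71 ± 0.22).

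In the inflammatory metabolism list 6 of 31 fell and 3 rose (9 and 4 adjusted over the list alone), with Hdc, which makes histamine, at -3.94 ± 0.56 (1 of 2 tolerant + LPS arrays at background). Nos2 was not called (-2.25 ± 0.66, limma adjusted p = 0.0798) but passed with the replicate block (0.0288), with -2.55 and -1.95 in replicate sets 1 and 2 and an adjusted p from 0.0288 to 0.31 over the alternatives. In the Toll-like receptor pathway Map3k8 (-1.81 ± 0.30), Rel (-2.09 ± 0.44) and Tlr3 (-1.82 ± 0.41) fell out of 33 (6 fell and 2 rose adjusted over the list alone). Of 26 antigen presentation genes 3 fell, Cd83 (-3.13 ± 0.31), Cd40 (-2.48 ± 0.31) and Cd69 (-1.85 ± 0.27), and Cd1d1 rose (5 and 2 adjusted over the list alone). Of 37 cell-cycle genes 5 fell (5 adjusted over the list alone): Stmn1, Cenpa, Ccnb2, Mki67 and Ube2c. In these lists 13 cell-cycle, 10 interferon-stimulated, 7 Toll-like receptor pathway and 7 antigen presentation genes fell with the replicate block. The median difference of the cell-cycle list was -2.11 in replicate set 1 and -0.58 in set 2. Of 30 cholesterol and lipid genes 6 fell and 2 rose (8 and 2 adjusted over the list alone), with the sterol synthesis genes Cyp51 (-2.24 ± 0.28), Idi1 (-2.92 ± 0.45) and Fdft1 (-2.04 ± 0.41) among those that fell. Of 14 alternative activation genes Mrc1, the lectin gene Clec10a (at least 5.89-fold) and Il4ra (-2.27 ± 0.23, and -2.32 to -0.35 over its probe sets) fell (3 adjusted over the list alone).

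The largest rises, apart from Marco, were of Ppp1r12b (4.88 ± 0.45, although another of its probe sets gave -0.05), Lhfpl2 (4.82 ± 0.84), Plpp1 (4.21 ± 0.79), Narf (3.77 ± 0.40), Osbpl3 (3.75 ± 0.41), Sirpb1a (3.69 ± 0.31) and the stress transcription factor gene Ddit3 (3.51 ± 0.47, and 1.22 on its other probe set). The largest falls, apart from those above, were of Tiam1 (-5.03 ± 0.51, 1 of 2 tolerant + LPS arrays at background), the gap junction gene Gja1 (-4.99 ± 0.50, and -4.99 to -1.07 over 6 probe sets), Edn1, which encodes endothelin-1 (-4.91 ± 1.16, 1 array), Ccnb2 (at least 14.3-fold), Mamdc2 (at least 8.91-fold) and Vcan (-4.21 ± 0.58, 1 array, and -2.78 on its other probe set). With camera the cytokine (adjusted p = 7.66e-10), interferon-stimulated (2.41e-08), chemokine (0.000349), cell-cycle (1.61e-09) and alternative activation (1.27e-05) lists were lower than the other genes. None of these held with an estimated correlation: the adjusted p was 0.127, 0.36, 0.148, 0.379 and 0.0828. The correlations estimated were 0.112, 0.534, 0.0513, 0.741 and -0.0505. For alternative activation the estimate lay below the fixed value, so correlation among its members does not account for its loss. The feedback inhibitors list, with an estimate of -0.00326, likewise went from an unadjusted camera p of 2.39e-05 to 0.0169. The alternative thus weakened lists without any positive correlation. For the other lists the part of correlation was not separated from such other differences between the settings. The median of cytokines was -2.04 and -1.94 in replicate sets 1 and 2, of interferon-stimulated genes -0.51 and -0.55, and of chemokines -0.47 and -0.65. With limma 488 genes were higher and 386 lower, and centring on the median gave 277 and 528 (55.8% against 34.4% higher). With the replicate block the counts were 1129 and 747. Fewer genes were called with any 1 array left out, and within each LPS group the counts depended on which one. More genes were called without naive + LPS replicate 1 than without replicate 2. More were also called without tolerant + LPS replicate 2 than without replicate 1. The untreated arrays do not enter this difference, and without either of them Ccl5 (0.053), Acod1 (-0.0629) and Ifnb1 (-0.76) kept their log2 differences. Leaving out an array of any group also lowers the residual degrees of freedom of the fit, equally for both arrays of a group. That loss therefore does not explain the gaps between replicates of an LPS group. Its part in the fall from the full counts was not separated from the effect of the array itself.

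Genes induced by LPS in naive cells (adjusted p under 0.05 and a log2 difference of at least 1) numbered 745. On restimulation 239 of them were lower in tolerant + LPS than in naive + LPS cells, 8 were higher and 498 were not called. The retained response, the difference between tolerant + LPS and untreated cells divided by that between naive + LPS and untreated cells on the log2 scale, had a median of 0.57 (0.555 in replicate set 1 and 0.58 in set 2). Among those with a log2 induction of at least 2, Tiam1 (-1.31), Chst11 (-0.406) and Jarid2 (-0.377) had the lowest retained response. Tiam1 was called below untreated cells (-2.85, limma adjusted p = 0.0206). For Chst11 and Jarid2 the negative value is a point estimate and not a call of a level below untreated cells. Lcn2 (1.74), Smad6 (1.73), Ptges, a prostaglandin E synthase (1.54), and Cfb (1.43) were among the highest. Of the 239 lower genes 43 were still called above untreated cells. With the replicate block 105 of 383 were, and after median centring 77 of 357. Of 1189 LPS-repressed genes 275 were higher in tolerant + LPS cells and 4 were lower, with a median retained response of 0.443. The number higher was 141 of 527 after median centring and 526 of 1564 with the replicate block. It was 86 and 73 without untreated replicates 1 and 2, 66 and 29 without naive + LPS replicates 1 and 2, and 27 and 109 without tolerant + LPS replicates 1 and 2.

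Because induced genes were chosen on arrays that also enter the second comparison, arrays were simulated in which tolerant cells kept the naive + LPS means. Over 100 draws at most 1 induced gene was called lower. No gene differs between the 2 LPS groups in such arrays, which yields almost no calls. This count therefore does not show what the choice of genes adds where some genes change. The median retained response lay between 0.957 and 0.986, against 0.57 in the data. The simulated arrays gave a median of 993 induced genes, against 745 in the data, and had no replicate effect. When genes with a log2 rise of at least 2 were chosen on 1 replicate set and measured on the other, 82% (399 genes, chosen on set 1) and 82.9% (461 genes, chosen on set 2) were lower in tolerant + LPS cells there. With the replicate block 383 of 866 induced genes were lower, and with median centring 357 of 1120. The number lower was 143 and 130 without untreated replicates 1 and 2, 57 and 28 without naive + LPS replicates 1 and 2, and 48 and 187 without tolerant + LPS replicates 1 and 2.

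Among induced genes, 9 of 15 cytokines were lower on restimulation (60%, against 31.5% of the other induced genes; two-sided Fisher's exact p = 0.0256). For chemokines the count was 1 of 13 (7.69%; exact p = 0.0718), for interferon-stimulated genes 6 of 37 (16.2%; exact p = 0.0452) and for antimicrobial genes 0 of 9 (exact p = 0.0644), of which 2 were higher. The median retained response was 0.527 for cytokines, 0.864 for chemokines, 0.792 for interferon-stimulated and 1.07 for antimicrobial genes. None of the 10 lists passed after Benjamini-Hochberg adjustment (adjusted exact p = 0.18 for these 4), and 2 had an unadjusted exact p under 0.05. With the replicate block 12 of 15 cytokines and 1 of 14 chemokines were lower, and both passed (adjusted exact p = 0.0379 each). After median centring, without naive + LPS replicate 1 and without tolerant + LPS replicate 2, 1 list passed in each case.

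**Figure D2:**
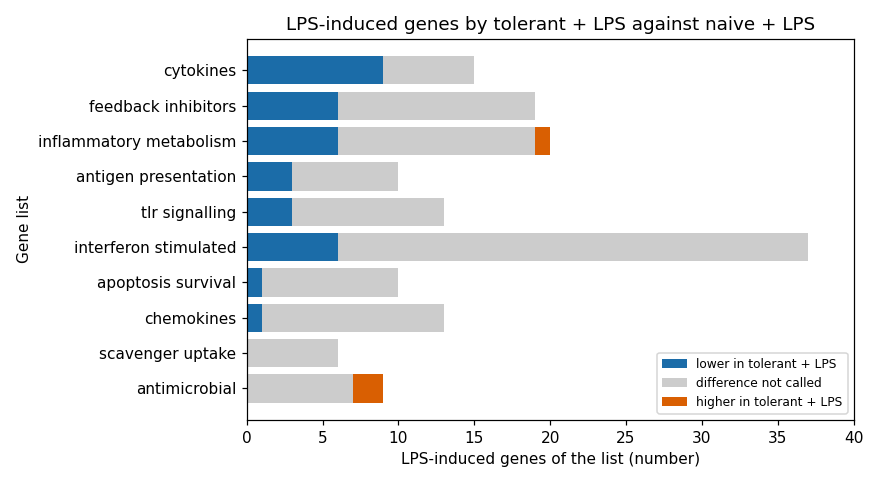
Number of LPS-induced genes of each fixed list (horizontal axis) that were lower, not called or higher in tolerant + LPS against naive + LPS cells, as stacked bars. Cytokines have 9 of 15 lower, chemokines 1 of 13 and antimicrobial genes 0 of 9, and no list passed the adjusted test with all arrays, the authors' scaling and no replicate block.

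**Figure D3:**
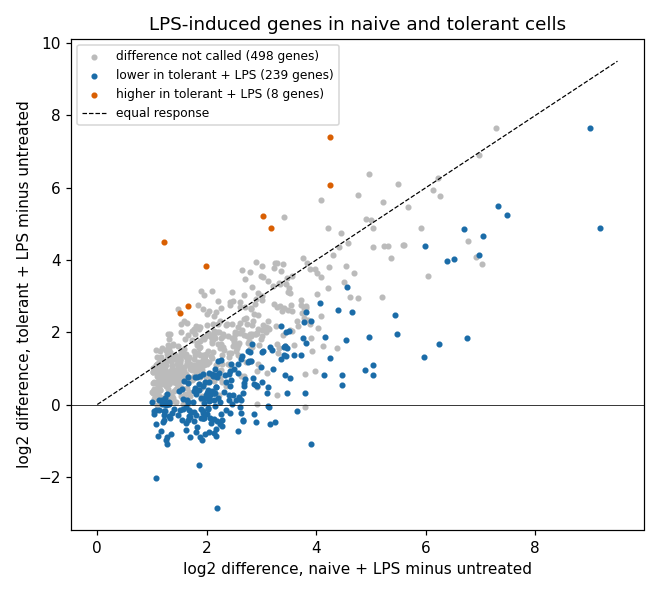
Log2 difference from untreated cells in naive + LPS (horizontal axis) and tolerant + LPS cells (vertical axis) for the 745 LPS-induced genes, 1 point per gene, coloured by the test between the 2 LPS groups. The dashed line marks an equal response, and the 239 genes called lower lie under it.

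Against untreated cells, restimulated tolerant cells had higher levels of most tested chemokine, interferon-stimulated and antimicrobial genes and lower levels of some cell-cycle and some cholesterol and lipid genes. Of these 5 lists, only the antimicrobial shift held with an estimated correlation. Lcn2 was higher by a log2 difference of 7.39 ± 0.24 (1 of 2 untreated arrays at background, n = 2 per group), Cxcl11 at least 100-fold, Cxcl9 at least 110-fold, Acod1 by 6.91 ± 0.96, Ccl5 by 6.27 ± 0.38 and the formyl peptide receptor gene Fpr2 by 6.37 ± 0.38. The other probe set of Cxcl11 gave 2.02 and that of Cxcl9 3.08. Il6 was still at least 12.5-fold above untreated cells, Tnf 21.3-fold (4.41 ± 0.32) and Il1b 17.6-fold (4.13 ± 0.32). Il12b (2.13 ± 0.64, limma adjusted p = 0.0937), Lipg (1.32 ± 0.45, 0.127) and Ifnb1 (1.73 ± 0.64, 0.148) passed only under some settings. With the replicate block all 3 passed (0.0305, 0.0382 and 0.0462), and their differences were 1.79, 0.86 and 1.73 in replicate set 1 and 2.46, 1.78 and 1.73 in set 2. Over the alternatives the adjusted p ran from 0.0305 to 0.266, from 0.0382 to 0.368 and from 0.0462 to 0.415.

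Of 40 interferon-stimulated genes 35 rose (39 adjusted over the list alone), with Oasl1 at 5.93 ± 0.38 and Isg20 at 5.14 ± 0.36. Of 19 chemokine genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), including Cxcl10 (5.76 ± 0.24) and Ccl8 (3.91 ± 0.38). Of 24 antimicrobial genes 13 rose and 1 fell (17 and 1), with Cfb at 6.08 ± 0.27, Marco at 5.87 ± 0.84 and Clec4e, a receptor for mycobacterial glycolipid, at 4.05 ± 0.26. For Marco 1 of 2 untreated arrays was at background, and its difference was 4.06 in replicate set 1 and 7.67 in set 2. Of 19 cytokine genes 7 rose (8 adjusted over the list alone), and of 32 feedback inhibitors 15 (19), with Il1rn at 4.87 ± 0.19, Socs3 at 4.66 ± 0.23 and Cd274, which encodes the checkpoint ligand PD-L1, at 3.75 ± 0.21. Of 31 inflammatory metabolism genes 13 rose (21 adjusted over the list alone, and 21 with the replicate block), with Ptges at 4.88 ± 0.38.

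Of 37 cell-cycle genes 10 fell and none rose (29 fell adjusted over the list alone, and 28 with the replicate block). Ccnb2, the mitotic cyclin B2, was at least 24-fold lower, Cenpa, a centromere histone, fell by 4.36 on the log2 scale, Stmn1 by 3.74 and Mki67, the proliferation marker Ki-67, by 2.44. The list's median was -3.42 in replicate set 1 and -1.69 in set 2. Its median signal was 2800 and 718 on the untreated arrays and 158 and 150 on the tolerant + LPS arrays, replicates 1 and 2. Of 30 cholesterol and lipid genes 9 fell and 1 rose (17 and 1 adjusted over the list alone; 14 and 1 with the replicate block), with the sterol synthesis genes Cyp51 (-2.05 ± 0.28) and Sqle (-2.03 ± 0.35) lower and the oxysterol receptor gene Nr1h3 higher (1.83 ± 0.31). Of 14 alternative activation genes 5 fell and 1 rose (5 and 1), with Mrc1 at -5.30 ± 0.29 and Clec10a at least 16-fold lower.

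With camera the interferon-stimulated (adjusted p = 2.22e-33), chemokine (4.29e-11) and cytokine (3.08e-08) lists were higher, and the cell-cycle (1.18e-10), cholesterol and lipid (1.39e-06) and alternative activation (0.0354) lists lower. With an estimated correlation the adjusted p was 0.148, 0.0812, 0.134, 0.36, 0.134 and 0.187. The alternative activation list did not pass with the replicate block (adjusted p = 0.0752). The antimicrobial, feedback inhibitor and inflammatory metabolism lists held (adjusted p = 0.0407 each with an estimated correlation). With limma 457 genes were higher and 435 lower, and centring on the median gave 617 and 304 (51.2% against 67% higher). With the replicate block the counts were 740 and 916. They were 255 and 143 without untreated replicate 1, 180 and 65 without untreated replicate 2, 178 and 137 without tolerant + LPS replicate 1, and 267 and 443 without tolerant + LPS replicate 2.

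Both comparisons with untreated cells use the same 2 untreated arrays. Across genes their log2 differences correlated at 0.662, against 0.498 in simulations of unchanged groups, and the covariance was 0.705 against 0.0863. Genes called higher in both numbered 321 and lower in both 208, where independent lists of these sizes would share 33.5 and 51.3. These overlaps were not recounted with 1 untreated array left out, where fewer genes were called in each comparison. The simulations shared at most 1, since unchanged groups yield almost no calls, so they do not show what the shared arrays add among genes that change. The untreated arrays were not split between the comparisons, since each would keep only 1, and part of this excess may come from sharing them.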

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

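Probe sets outside the named genes also carried an LPS signal. Of 2567 probe sets with no symbol above the same filter, 127 were higher in naive + LPS than in untreated cells and 146 lower (limma, adjusted p under 0.05). Of 579 probe sets with several symbols 35 were higher and 23 lower. They were picked out because no comparison of the report uses them. Groups of 2 arrays are too small for Dixon's outlier test, so single arrays were instead weighted by the fit or left out in turn.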

How the results depend on the processing

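Each called named result kept its sign under each alternative that gave it a value. Of 228 called named results, 48, 53, 61, 76, 80 and 45 lost their call without untreated replicates 1 and 2, naive + LPS replicates 1 and 2 and tolerant + LPS replicates 1 and 2, where the lone array is assumed to vary like the other groups, and 99 did at an adjusted p under 0.01. Differences that were not called turned sign between tolerant + LPS and naive + LPS cells: Ccl5 was -0.121 after median centring, Acod1 0.0317 after quantile normalization, and with 1 array left out Ccl5 ran from -0.0774 to 0.183, Acod1 from -0.149 to 0.0237 and Ifnb1 from -1.74 to 0.22. Low signal limits the folds of genes at background, and the number of arrays limits the rest. In what follows A is naive + LPS against untreated, B tolerant + LPS against naive + LPS, and C tolerant + LPS against untreated.

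After median centring A had 537 lower genes, B had 277 higher, 141 LPS-repressed genes were higher in tolerant + LPS cells, and 1 list was set apart among induced genes by Fisher's exact test, against 0. After quantile normalization A had 816 lower and 166 repressed genes were higher. Without the filter B had 304 higher and 171 repressed genes were higher. With every probe set A had 1222 higher, 5 induced genes were higher in tolerant + LPS cells, and the median retained response was 0.551; it was 0.549 with the mean over probe sets and 0.543 with a pseudocount of 64. Without the trend B had 293 higher and 239 lower, C had 290 higher, and 155 induced genes were lower and 5 higher. With fits of 2 groups B had 191 higher, 108 repressed genes were higher and the retained response was 0.55. With array weights B had 323 higher. At an adjusted p under 0.01 A had 400 higher and 318 lower, B 31 and 47, C 133 and 65; 34 induced genes were lower and 1 higher, 23 repressed genes were higher, and the retained response was 0.594. With an induction of at least 2, 152 induced genes were lower and 4 higher, 122 repressed genes were higher, and the retained response was 0.602. With an estimated correlation 6 of 54 list shifts passed, against 35. The stricter threshold and the smaller sets give fewer genes by construction; for the other settings the cause was not tested.

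With the replicate block A had 2008 lower, B 1129 higher and 747 lower, C 740 and 916; 383 induced genes were lower and 16 higher, 526 repressed genes were higher, and 2 lists were set apart. Every gene called without the block was also called with it. Leaving out 1 array at a time gave 419 to 842 higher and 233 to 1429 lower genes in A, 34 to 189 and 43 to 322 in B, and 178 to 347 and 65 to 443 in C. Induced genes lower ranged from 28 to 187 and higher from 1 to 8, repressed genes higher from 27 to 109, the retained response from 0.531 to 0.643, list shifts from 32 to 39 and lists set apart from 0 to 1.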

Other observations

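Some genes set restimulated tolerant cells apart from both other groups. Tolerant + LPS cells were higher than both in 72 genes and lower than both in 93, where independent lists would share 20.4 and 15.4. Simulations of unchanged groups shared at most 1, since they yield almost no calls, so they do not show what the shared tolerant + LPS arrays add. Across all genes the 2 comparisons correlated at 0.261, under the 0.501 of simulated unchanged groups, with a covariance of 0.216 against 0.0872. Part of the excess may come from the tolerant + LPS arrays that both comparisons share, and the counts were 174 and 239 with the replicate block and 60 and 93 after the median centring. They were not recounted with 1 array left out, where fewer genes were called between the 2 LPS groups. The higher group, ranked by the smaller of its 2 differences, included Plpp1 (4.21 against naive + LPS and 5.24 against untreated cells), Marco (3.94 and 5.87), Osbpl3 (3.75 and 3.63), the acute phase gene Orm1 (3.44 and 4.88), Lcn2 (3.14 and 7.39), Pla2g7, which encodes an acetylhydrolase of platelet-activating factor (2.56 and 2.38), and Hp (2.35 and 3.31). The lower group included Mrc1 (-4.94 and -5.30), Igfbp4 (-3.43 and -4.32), Crip1 (-3.48 and -3.42), Clec10a (-3.34 and -4.78), Stmn1 (-3.30 and -3.74) and the sterol synthesis gene Fdps (-3.22 and -3.48). These genes were chosen after their values were seen, except those the fixed rule names.

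Of the tests that follow, the 2 on scaling, that on the replicate sets and that on members at or over the signal ceiling were chosen after the result was seen. Cytokines, chemokines and interferon-stimulated genes differed in how many induced members were lower on restimulation, although no list passed the adjusted test with all arrays, the authors' scaling and no replicate block. A ceiling of the array does not account for members with a naive + LPS mean under 13 on the log2 scale, since 0% of 10 chemokine and interferon-stimulated members were lower there against 35.5% of 552 other genes (Fisher's exact p = 0.0175). The value of 13, a signal of 8192, was a chosen level and not a measured saturation point. The highest signal of an array ran from 33430 to 51390. For the 40 members at or over the chosen level, 17.5% were lower against 25.2% of 143 others (Fisher's exact p = 0.4). So for Ccl5, Cxcl10 and others this bright a ceiling that hides a fall cannot be told apart from a kept response. Their level and size of induction may account for the rest, but the test does not decide it. Against 10000 random induced lists matched on both, the median retained response lay inside the central 95% in each case. It lay at percentile 94.4 for chemokines, 96.8 for interferon-stimulated genes and 6.33 for cytokines. Each draw left out only the tested list's own members. Lists matched to chemokines could therefore hold interferon-stimulated genes, and the reverse, and so carry part of the pattern. A different effect of the pretreatment on these groups of genes stays open.

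More genes were called lower than higher after LPS in naive cells. With each array rescaled to its mean after trimming 20% at each end, the median difference of all genes went from -0.31 to 0.04, but this moved all genes nearly alike (by a median of 0.359 with an SD of 0.0248 over genes), so a median near 0 follows from the rescaling and decides nothing about the authors' scaling. The spiked control transcripts were higher on the naive + LPS arrays by 0.44 on average (0.655 and 0.225 in the replicate sets), but the untreated arrays differed by 0.409 from each other, so the spikes do not decide whether the scaling lowered the naive + LPS arrays as a whole. That scaling, a larger share of the labelled RNA taken by the brightest genes and a loss of many transcripts in LPS-treated cells cannot be told apart, since no value here fixes the amount of RNA per cell.

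Cell-cycle genes were lower in tolerant + LPS than in untreated cells. A difference between the replicate sets does not account for it, since the list's median fell in both, the smaller fall being -1.69. Nor does a loss of signal shared by genes of that level: the list's median of -2.56 lay at percentile 0 of 10000 lists matched on the untreated level, whose central 95% ran from -0.417 to 0.084. That percentile reflects the draw of genes, which need not move together as this list does (estimated correlation 0.741). It does not measure the spread between cultures. The untreated level itself differed between replicates (median signal 2800 and 718, mean log2 11.12 and 9.404). That gap is of the same order as the smaller fall, and how much the cultures were dividing was not recorded in the labels. An effect of the LPS exposures on cell division stays open and was not tested. Counting cells in S phase in untreated, naive + LPS and tolerant + LPS cultures would test it. The list's shift did not pass with an estimated correlation (adjusted p = 0.36).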
